A study of Homo sapiens with 17 samples.

How the data were processed

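Messenger RNA of PC3M human prostate cancer cells was measured in 17 libraries prepared, per the labels' protocols, with QuantSeq FWD, which reads 1 tag per transcript near its 3' end. Per the labels, the cells carried a non-targeting siRNA (siNT), an siRNA against JMJD6 (siJMJD6) or a knockout (KO) of HSF1, and were given DMSO, the proteasome inhibitor MG132 or heat shock. Grouping by label gave 7 groups, with 2 libraries in each of 4 groups of the MG132 table and 3 in each of 3 groups of the heat shock table, and all 17 columns were matched to a label. The letters A and B of the KO libraries were taken as 2 replicates, since the labels do not say whether they are separate clones.

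The signal values are the authors' normalized counts, deposited as 1 table per experiment with 14085 genes (MG132) and 13616 genes (heat shock). Per the submitters' processing notes, reads were checked with FastQC 0.11.2, aligned with STAR 2.6.0 and counted per gene with HTSeq (version not stated) on build hg38 of the human genome. The roles of these tools are taken from their usual purpose. Gene annotation, strand setting, gene filter and scaling method are not given in the sources used here. The values are not whole numbers, the steps of 1 read differ from gene to gene, and libraries of low depth hold small positive values in place of 0. Counts adjusted to a common library size by matching quantiles of a count distribution look like this. Because whole reads could not be recovered in all libraries, the values were analysed on the log scale. The tables were normalised separately, so every test stayed within 1 table, and only effects were set side by side between them.

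Log2 values of the normalised count plus 1 were fitted with limma 3.58.1 in R 4.3.3, with moderated variances following a trend with mean level. All groups of a table shared 1 estimate of spread per gene. Genes were tested where at least 10 normalised counts were reached in as many libraries as the smallest group holds, 2 in the MG132 table and 3 in the heat shock table, which left 9778 and 9831 genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. There were 6 comparisons, namely MG132 against DMSO, siJMJD6 against siNT under MG132, HSF1 KO against siNT and against siJMJD6 under MG132, heat shock against basal, and siJMJD6 against siNT after heat shock. Replicate numbers were not used as pairs. The tests, lists, alternatives and rule for naming genes were fixed before the data were examined.

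Genes were named by a rule. It takes JMJD6 and HSF1, and a panel of HSPA1A, HSPA1B, HSPA8, HSPH1, HSP90AA1, DNAJB1, HSPB1 and BAG3 in every comparison. It adds the 6 largest rises and 6 largest falls among called genes whose groups did not overlap and whose mean was at least 50. From each list it takes up to 4 called members with the smallest adjusted p, or, where none was called, the values of the 2 with the smallest p. Other named genes are said to be chosen after their values were seen.

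Of 24 gene lists written from general knowledge, 23 had genes in the tables. They held cytosolic chaperones and co-chaperones (44 genes, 39 in the tables), TRiC and prefoldin subunits (14), proteasome subunits (34), ubiquitin and autophagy genes (20), folding genes of the endoplasmic reticulum (20), ATF4 and CHOP targets (24), NRF2 targets (20), metallothioneins (10), immediate-early genes (22), NF-κB cytokines (18), interferon-response genes (21), growth arrest and damage genes (16), S phase genes (24), mitotic genes (24), splicing regulators (24), cholesterol synthesis genes (20), hypoxia and glycolysis genes (18), JmjC oxygenases (24) and ribosomal proteins (40). Lists of epithelial (10), mesenchymal (14), androgen receptor-positive prostate (10) and blood and immune genes (11) describe cell identity, and genes of mitochondrial DNA (13) had 0 members in the tables. The list of cytosolic chaperones also holds HSPD1 and HSPE1 of mitochondria and SERPINH1 of the endoplasmic reticulum. Older symbols were used for 5 genes. Each list was tested with limma's camera against all other tested genes, with a preset correlation of 0.01 between genes and again with a correlation estimated from the data, adjusted over the lists of a comparison. Members were also adjusted over the list alone.

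Overlaps between sets of called genes were tested with a one-sided exact Fisher test, in a family of 7 planned and a family of 9 further overlaps. For overlaps whose comparisons share siNT libraries, 100 draws of simulated tables, in which the third group had no effect, gave the covariance of effects that sharing alone makes. The simulated groups had too few lower calls to show how much of an overlap sharing makes. After the overlaps had been seen, the siNT stress libraries were also split in every way, with some used for the stress effect alone and the rest for the knockdown or knockout effect alone, in 1 fit with a common spread per gene. In these draws uncalled genes had no stress effect. A first version used the observed group means of all genes and was replaced after its result was seen.

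Reads per library were estimated from the steps between low values, assuming a dispersion of 0.05, at 0.63 M to 2.93 M. Per library 36.2% to 100% of the low values checked lay near a whole read, so some estimates are uncertain. At such depths genes of low level are likely to be measured poorly, which was not tested by level. On simulated data in which 200 genes were changed, 100 of them 2-fold and 100 4-fold, the fit recovered 70% and 99% for heat shock, 78% and 98% for siJMJD6 after heat shock, 17% and 69% for MG132, 20% and 72% for siJMJD6 under MG132, 16% and 76% for KO against siNT and 14% and 68% for KO against siJMJD6. Between 4.17% and 6.63% of its calls were false. Camera tested on simulated data called the 1 list that was moved and 0 of the others. The simulated genes varied independently of one another, so this does not check the preset correlation.

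The alternatives were pseudocounts of 0.5 and 10, no filter on low values, a filter at 50, rescaling by TMM (trimmed mean of M values), quantile normalisation, a fit of only the 2 groups compared, a block for the replicate number and leaving out each library in turn. In the fit with a block, KO libraries A and B, which carry no replicate number, were given no block term. Sample weights were added after the data were seen. Coordinates are those of GRCh38, the same build as hg38, looked up by gene symbol. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for depth, sequence checks and plots. Raw reads and protein data were not used here.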

Results

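Gene expression was measured in PC3M, an established line of human prostate cancer cells, by sequencing 1 tag from the 3' end of each captured transcript. The study asked how the stress transcription factor HSF1, the oxygenase JMJD6 and the heat shock proteins are linked when proteins misfold. The 17 libraries fell into 7 groups and were given in 2 separately normalised tables. The first table held 8 libraries. Cells transfected with a non-targeting siRNA (siNT) received the solvent DMSO (n = 2) or the proteasome inhibitor MG132 (n = 2), and cells transfected with an siRNA against JMJD6 (siJMJD6, n = 2) and HSF1 knockout (KO) cells (libraries A and B, n = 2) received MG132, at 2.5 µM for 4 hours. The second table held 9 libraries, with 3 each of siNT cells without stress (basal), siNT cells after heat shock and siJMJD6 cells after heat shock. Heat shock was 1 hour at 42 °C with 2 hours of recovery, and siRNA transfection lasted 72 hours. Unstressed siJMJD6 or KO cells were not analysed here, so a difference between groups under stress could not be separated from one present before stress.

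The tables listed 14085 genes (MG132) and 13616 genes (heat shock), of which 9778 and 9831 passed the filter on low values and were tested. Column totals lay between 1505826 and 1819640 normalised counts. The reads behind them, estimated from the steps between low values, lay between 0.63 M (siNT basal library 3) and 2.93 M (siNT basal library 2). Only 41.6% and 36.2% of the low values checked there lay near a whole read, against 100% in siNT heat shock library 1. Both estimates are therefore uncertain. Ribosomal protein gene RPS24 held the largest share of every library, from 2.28% to 3.78%. Log2 values of replicate libraries correlated across genes at r = 0.967 to 0.977 in the heat shock table and 0.919 to 0.953 in the MG132 table. The median standard error (SE) of a log2 fold change was 0.195 in the heat shock table and 0.394 in the MG132 table. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. Group values are normalised counts as mean ± SD, effects are log2 fold changes ± SE, and adjusted p is the Benjamini-Hochberg value of limma's test. A gene is said to rise or fall only where adjusted p was under 0.05, and the largest rises and falls are those of called genes with a mean of at least 50 and groups that did not overlap.

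The targeted genes followed the labels. JMJD6 (chromosome 17, 76712832 to 76726799 in GRCh38) had 26.6 and 16.6 normalised counts in the siJMJD6 MG132 libraries, against 167 and 129.8 in siNT cells under MG132, 88.7 and 70.9 in DMSO and 80.5 and 79.4 in KO libraries A and B. After heat shock its mean was 10.7 ± 3.58 in siJMJD6 cells and 224 ± 25.3 in siNT cells, against 104 ± 1.41 at baseline. HSF1 (chromosome 8, 144291591 to 144314722) had 285 and 175 normalised counts in KO libraries A and B, against 1687 and 1884 in siNT cells under MG132. The tags lie at the 3' end of HSF1 and the deleted part is not given in the sources used here, so this lower level does not check the deletion itself.

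**Figure D1:**
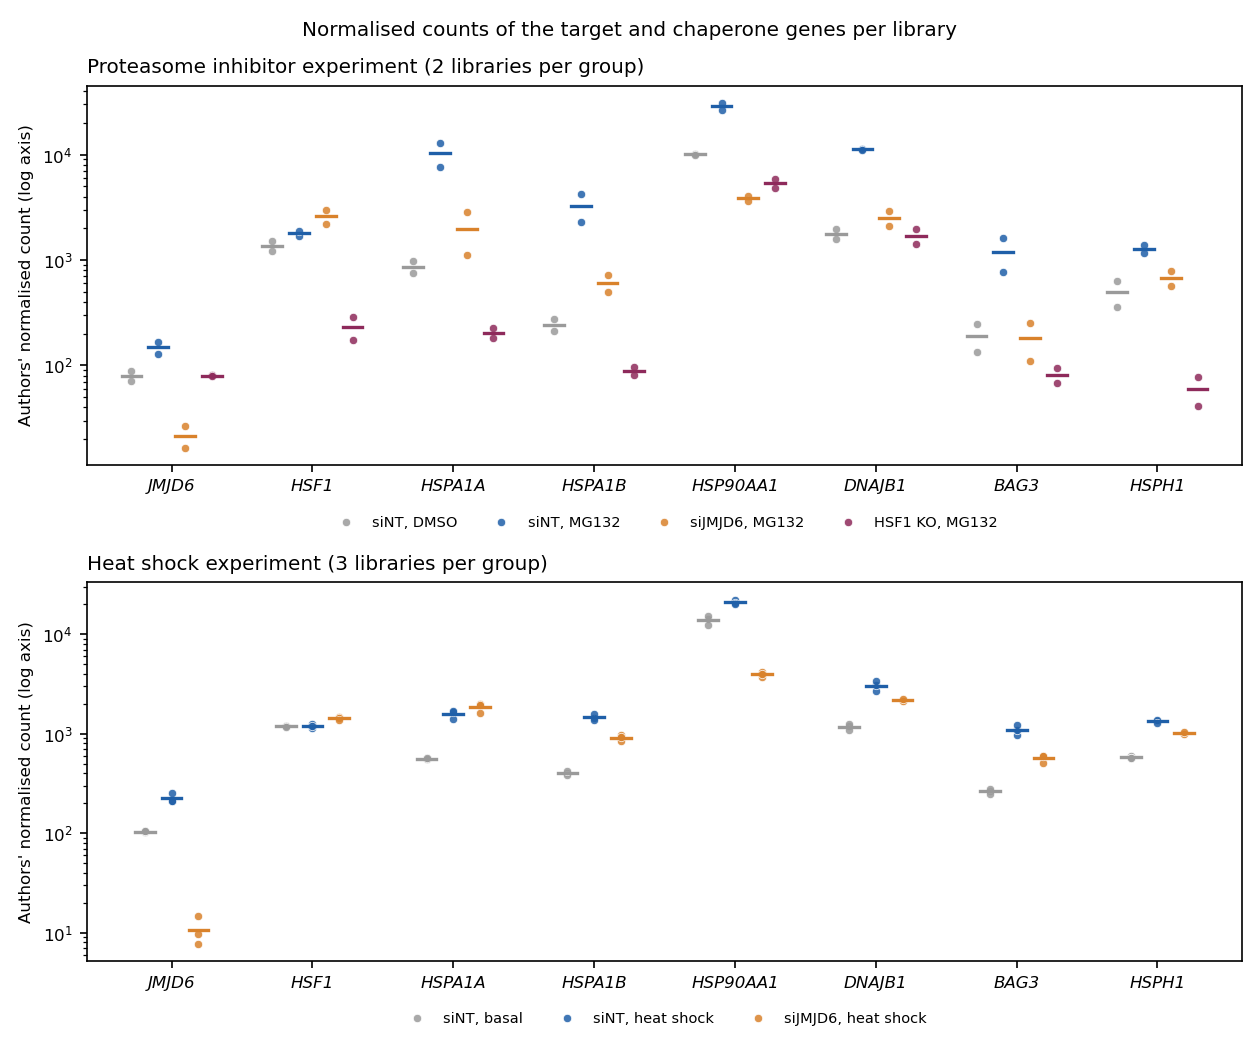
Normalised counts (log axis) of JMJD6, HSF1 and 6 chaperone genes in each library of the MG132 and heat shock tables, with dots for libraries and bars for group means. HSP90AA1 averaged 28719 in siNT cells under MG132 and 3851 in siJMJD6 cells, and HSPA1A averaged 205 in HSF1 KO cells.

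MG132 blocks the proteasome, and the first comparison asked what it does to siNT cells (2 MG132 against 2 DMSO libraries). It raised the inducible HSP70 genes strongly. HSPA1B rose from 243 ± 45.4 to 3270.2 ± 1355 normalised counts, a log2 fold change of 3.69 ± 0.30, adjusted p = 0.000115. HSPA1A rose by 3.53 ± 0.38, adjusted p = 0.000455. The HSP40 partner DNAJB1 rose by 2.66 ± 0.25, adjusted p = 0.000355, and the HSP70 co-chaperone BAG3 by 2.61 ± 0.43, adjusted p = 0.0169. HSP90AA1, the inducible HSP90, rose by 1.51 ± 0.23, adjusted p = 0.0113. TBX3, a developmental repressor, rose from 35.2 ± 1.70 to 488 ± 205 (3.69 ± 0.37, adjusted p = 0.000381). In all 26 of 9778 genes were called, 20 higher and 6 lower, all by at least 2-fold. JMJD6 had 79.8 ± 12.6 normalised counts in DMSO and 148 ± 26.1 in MG132, an effect of 0.88 ± 0.32 that was not called (adjusted p = 0.696). Values without a call were also seen for HSF1 (0.40 ± 0.27), HSPH1 of the HSP110 family (1.41 ± 0.33), the small heat shock protein HSPB1 (0.90 ± 0.25) and the constitutive HSP70 gene HSPA8 (0.63 ± 0.34).

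Genes outside the chaperone list were also called under MG132. ZFAND2A, which helps the proteasome handle damaged proteins, rose by 3.09 ± 0.33 and the ubiquitin ligase gene TRIM26 by 2.72 ± 0.32. PPP1R15A, which directs the phosphatase of eIF2α, rose by 2.56 ± 0.28, the stress transcription factor DDIT3 by 1.41 ± 0.26 and haem oxygenase HMOX1 by 2.45 ± 0.38. So did the growth arrest gene GADD45B (1.95 ± 0.30), IER5, which acts on HSF1 (2.01 ± 0.25), and the TNF family ligand TNFSF9 (2.67 ± 0.29). TXNIP, an inhibitor of thioredoxin and glucose uptake, fell from 268 ± 40.7 to 38.2 ± 10.1 normalised counts (−2.79 ± 0.30). The ERK phosphatase gene DUSP6 changed by −2.28 ± 0.29 and the early response factor KLF6 by −2.19 ± 0.37. Adjusted p for these 11 genes lay between 0.000455 and 0.0383.

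Of 34 tested cytosolic chaperones and co-chaperones under MG132, 5 rose, 0 fell and 29 were not called (10 rose when adjusted over the list alone). Camera placed the list above other genes (adjusted p = 1.49e-13, and adjusted p = 0.17 with an estimated correlation). The 5 were HSPA1A, HSPA1B, DNAJB1, BAG3 and HSP90AA1. In the ubiquitin and autophagy list 2 of 19 rose (3 adjusted over the list alone, camera adjusted p = 8.48e-05, 0.388 with an estimated correlation). In the list of ATF4 and CHOP targets 2 of 23 rose (7, 1.16e-06, 0.381), and in the NRF2 list 1 of 17 (3, 0.000178, 0.381). By limma 0 of 34 proteasome subunits were called, and 4 had an unadjusted p under 0.05, all higher. PSMC3 of the cap had 0.66 ± 0.26 (camera adjusted p = 0.0131, 0.381 with an estimated correlation). Splicing regulators had 0 of 22 called and 2 higher at an unadjusted p under 0.05, with SRSF3 at 0.62 ± 0.27 (0.0144, 0.396). Mitotic genes had 0 of 24 called and 0 at an unadjusted p under 0.05, with AURKA at −0.49 ± 0.26 (0.0161 for lower values, 0.669). Of 20 folding genes of the endoplasmic reticulum (ER) 0 were called by limma, and 2 were higher both at an unadjusted p under 0.05 and adjusted over the list alone (camera adjusted p = 0.0581). The HSP70 of the ER, HSPA5, had 1.22 ± 0.28 and the ER degradation gene HERPUD1 1.11 ± 0.29.

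These MG132 counts rest on 2 libraries per group. Leaving out 1 library also lowers the power of the fit, so a lost call need not mean that it rested on that library. The number of called genes fell to 12 without either DMSO library and to 10 without siNT MG132 library 1. Without the filter on low values it was 6, chaperone calls were 2, and the calls of HSPA1A, HSP90AA1, BAG3, TBX3, ZFAND2A, TRIM26, DDIT3, HMOX1, GADD45B, KLF6 and DUSP6 were lost (adjusted p from 0.054 to 0.48). DDIT3 was also lost in a fit of the 4 libraries alone (0.0641). Chaperone calls were 3 without DMSO library 1 or siNT MG132 library 1. HSP90AA1 had 0.97 under quantile normalisation and was not called when any 1 of the 4 libraries compared was left out (adjusted p from 0.0634 to 0.24), nor were DDIT3, HMOX1, KLF6 and GADD45B (0.0516 to 0.386). BAG3 was lost without DMSO library 1, siNT MG132 library 1 or either KO library (0.0577 to 0.313). DUSP6 was lost without DMSO library 2 or siNT MG132 library 1 (0.0564 and 0.0568). HSPA1A, HSPA1B, DNAJB1, TBX3, ZFAND2A, TRIM26, TNFSF9, TXNIP, PPP1R15A and IER5 were called in every fit that left out 1 library.

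Heat shock was compared with baseline in siNT cells (3 libraries each). JMJD6 rose from 104 ± 1.41 to 224 ± 25.3 normalised counts, by 1.10 ± 0.18, adjusted p = 0.000103, while the level of HSF1 itself was flat (0.0078 ± 0.073, adjusted p = 0.98). BAG3 rose by 2.03 ± 0.094, HSPA1B by 1.85 ± 0.083, HSPA1A by 1.495 ± 0.084, DNAJB1 by 1.36 ± 0.078, HSPH1 by 1.19 ± 0.075, HSP90AA1 by 0.59 ± 0.069 and HSPB1 by 0.54 ± 0.077, with adjusted p from 1.23e-18 to 7.19e-06. HSPA8 had 0.0056 ± 0.11 (adjusted p = 0.988). The largest rises were in TBX3, from 45.3 ± 4.36 to 417 ± 60.9 (3.17 ± 0.13, adjusted p = 7.24e-20), and TRIM26 (3.03 ± 0.17, adjusted p = 2.9e-16). In all 402 of 9831 genes were called, 281 higher and 121 lower, of which 102 and 22 changed at least 2-fold. Under another scaling of the libraries (TMM) the split was 237 higher and 188 lower, so the share of higher calls moved from 69.9% to 55.8%.

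The ER folding genes rose together after heat shock. HSPA5 rose by 1.43 ± 0.066, adjusted p = 2.57e-18, HERPUD1 by 2.16 ± 0.097, the secreted ER factor MANF by 1.01 ± 0.090 and the ER co-chaperone SDF2L1 by 0.93 ± 0.085. Of 20 tested ER genes 14 rose, 0 fell and 6 were not called (17 rose adjusted over the list alone). Of 37 cytosolic chaperones 22 rose, 0 fell and 15 were not called (24 rose adjusted over the list alone). Camera placed both lists above other genes (adjusted p = 2.55e-18 and 8.32e-21), and both calls held with an estimated correlation (adjusted p = 0.00976 for each). Over all 6 comparisons of 23 lists, the only other camera calls that held so were ATF4 and CHOP targets and mitotic genes in siJMJD6 cells after heat shock. No subunit of the chaperonin TRiC or of prefoldin and no proteasome subunit was called after heat shock (limma, 0 of 14 and 0 of 34, with 4 and 3 higher at an unadjusted p under 0.05): CCT6A of TRiC had 0.21 ± 0.076 and PSMB3 0.42 ± 0.16.

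ZFAND2A (1.71 ± 0.16) and the ubiquitin gene UBB (0.49 ± 0.071) rose after heat shock. Of 23 ATF4 and CHOP targets 6 rose, among them DDIT3 (0.90 ± 0.12) and the stress sensor SESN2 (0.85 ± 0.12), and 2 fell. These were the mTOR inhibitor DDIT4 (−0.70 ± 0.11) and ATF4 itself (−0.36 ± 0.092), and camera gave adjusted p = 0.0369, or 0.2 with an estimated correlation. Among immediate-early genes 4 of 17 rose and 2 fell. They included IER5 at 0.89 ± 0.12, KLF6 at 0.65 ± 0.12, MCL1, which blocks cell death, at 0.41 ± 0.086 and IER2 at −0.58 ± 0.081. Of 22 splicing regulators 5 rose and 0 fell (6 adjusted over the list alone, camera adjusted p = 0.0108, 0.204 with an estimated correlation). They were led by the splicing component LUC7L (1.37 ± 0.21), the kinase CLK4 (1.39 ± 0.31) and SRSF11 (0.42 ± 0.097). Of 23 JmjC oxygenases 4 rose and 1 fell (camera adjusted p = 0.0455, 0.2 with an estimated correlation). Beside JMJD6 those that rose were the histone demethylase genes PHF8 (1.37 ± 0.12), KDM5A (1.16 ± 0.12) and JMJD1C (0.77 ± 0.14). The replication genes FEN1 and MCM4 changed by −0.50 ± 0.12 and −0.45 ± 0.12, the 2 calls among 21 S phase genes (camera adjusted p = 0.0369 for lower values, 0.225 with an estimated correlation). The glutamate transporter SLC1A3 rose by 2.01 ± 0.16. The largest falls were in acute phase gene SAA1 (−1.55 ± 0.27), the lipid synthesis gene DGAT2 (−1.54 ± 0.18) and the metallothionein MT1E (−1.39 ± 0.24), followed by the CDC42 effector CDC42EP2 (−1.16 ± 0.19), S100A9 of inflammation (−0.93 ± 0.21) and PIGW of membrane anchor synthesis (−0.85 ± 0.15).

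HSP90AA1 was not called after heat shock under quantile normalisation (0.12, adjusted p = 0.386), which sets the highest values of all libraries equal. Leaving out 1 library gave 273 to 428 called genes and ended the calls of ATF4, FEN1, MCM4 and SRSF11 in at least 1 of the 9 fits (adjusted p from 0.0507 to 0.141). ATF4 and MCM4 lost their calls without library 1 or 2 of either siNT group. FEN1 lost its call without library 1 of either siNT group, and SRSF11 without siNT basal library 3 or siNT heat shock library 1. CLK4 had 0.87 with a pseudocount of 10, and HSPA8 −0.15 without siNT heat shock library 3, still uncalled.

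Knockdown of JMJD6 was compared with siNT under MG132 (2 libraries each), to ask which genes depend on JMJD6 in stressed cells. HSP90AA1 fell from 28719 ± 2846 to 3851 ± 268 normalised counts (−2.90 ± 0.23, adjusted p = 1.66e-05). BAG3 (−2.73 ± 0.43), HSPA1A (−2.47 ± 0.38), HSPA1B (−2.38 ± 0.30), DNAJB1 (−2.18 ± 0.25) and HSPA8 (−1.65 ± 0.34) fell as well (adjusted p from 0.000278 to 0.00848). HSPH1 had −0.92 ± 0.33 (adjusted p = 0.0849), HSPB1 0.23 ± 0.25 (adjusted p = 0.589) and HSF1 0.52 ± 0.27 (adjusted p = 0.218). None of these was called. The deepest falls were in targets of ATF4, the transcription factor of the integrated stress response. DDIT4 went from 3128 ± 60.7 to 89.9 ± 35.3 (−5.16 ± 0.29, adjusted p = 7.73e-07) and CHAC1, which degrades glutathione, from 377 ± 45.0 to 16.9 ± 0.346 (−4.40 ± 0.26, adjusted p = 9.34e-07). In all 1327 of 9778 genes were called, 608 higher and 719 lower, of which 539 and 614 changed at least 2-fold. More were higher than lower in a fit of these 4 libraries alone (390 and 297), without siNT MG132 library 2 (409 and 306), without the filter on low values (355 and 320) and with a pseudocount of 10 (711 and 699).

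ATF4 and CHOP targets fell as a list with siJMJD6 under MG132. Of 23 tested members 16 fell, 0 rose and 7 were not called (18 fell adjusted over the list alone, camera adjusted p = 2.54e-09, adjusted p = 0.6 with an estimated correlation). Among them were asparagine synthetase ASNS at −2.90 ± 0.30 and the cystine transporter SLC7A11 at −2.94 ± 0.31. ATF4 is itself among the 16 list members that fell, and was named only after the other members were seen to fall. It changed by −2.17 ± 0.27, adjusted p = 0.00042, from 1072 and 1771 normalised counts in the siNT libraries to 346 and 269 in the siJMJD6 libraries. Of 34 cytosolic chaperones 10 fell, 0 rose and 24 were not called (13 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0163, 0.6 with an estimated correlation). The ER degradation gene HERPUD1 changed by −2.14 ± 0.29, the 1 called gene among 20 of the ER list, VBP1 of the folding complex prefoldin by −1.87 ± 0.31 and ZFAND2A by −1.44 ± 0.33.

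Genes of cell division fell with siJMJD6 under MG132. Of 24 mitotic genes 15 fell, 0 rose and 9 were not called (18 fell adjusted over the list alone, camera adjusted p = 5.24e-07, 0.6 with an estimated correlation). Among those that fell were the mitotic kinases AURKA (−1.84 ± 0.26, adjusted p = 0.000859) and PLK1 (−2.15 ± 0.40, adjusted p = 0.00466). Of 21 S phase genes 10 fell, 0 rose and 11 were not called (camera adjusted p = 0.00178, 0.643 with an estimated correlation). Examples were the nucleotide reductase subunit RRM1 at −1.47 ± 0.28 and the helicase subunit MCM7 at −1.28 ± 0.27. PRR11, another gene of dividing cells, changed by −3.34 ± 0.26. In the growth arrest list 3 of 14 rose and 1 fell, with CDKN2B, which blocks entry into S phase, at 1.62 ± 0.30. Of 22 splicing regulators 5 fell and 0 rose, with HNRNPA1 at −1.77 ± 0.23 and TRA2B at −1.75 ± 0.28. Interferon-response genes rose in 3 of 10 cases, ISG15 by 1.43 ± 0.27 and IFI6 by 2.46 ± 0.47, without a camera call (adjusted p = 0.133). Of 17 hypoxia genes 3 rose and 4 fell, with ANKRD37 at 2.75 ± 0.37 and the oxygen sensor EGLN3 at 2.93 ± 0.52. Of 19 cholesterol synthesis genes 2 rose and 5 fell, with INSIG1 at −2.09 ± 0.39. The growth arrest, splicing, hypoxia and cholesterol lists had no camera call either (adjusted p from 0.105 to 0.769). Of all tested genes 13.6% were called in this comparison.

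The largest rises with siJMJD6 under MG132 were in the short non-coding RNA SNAR-G1, a copy of a near-identical family whose reads may be split between copies (4.86 ± 0.62, adjusted p = 0.000472), and the kinase gene PSKH1 (4.59 ± 0.62, adjusted p = 0.000655). HOXA11-AS, an antisense transcript counted under a strand setting not given in the sources used here, rose by 4.03 ± 0.54, adjusted p = 0.000606. Next came the large scaffold gene AHNAK2 (3.40 ± 0.26, adjusted p = 1.47e-05), the interleukin receptor gene IL17RE (3.29 ± 0.27, adjusted p = 2.35e-05) and the fat cell gene ADIRF (3.16 ± 0.86, adjusted p = 0.0303). Beside DDIT4, CHAC1 and PRR11 the largest falls were in the spliceosomal RNA gene RNU5F-1 (−3.92 ± 0.44), the inositol phosphate kinase gene ITPK1 (−3.28 ± 0.36) and the collagen gene COL1A2 (−3.002 ± 0.39).

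Leaving out single libraries ended part of the siJMJD6 calls under MG132. How much of this is lower power and how much the values of that library was not tested. The count of called genes was 351 without siNT MG132 library 1, 715 without library 2 and 877 without siJMJD6 library 1. It was 862 and 863 without KO library A or B, which enter through the shared spread, 675 without the filter on low values, 687 in a fit of these 4 libraries alone and 696 with sample weights. Chaperone calls were 6 without siNT MG132 library 1. Without that library the calls of HSPA8, ADIRF, ISG15, RRM1, MCM7, INSIG1 and ZFAND2A were lost (adjusted p from 0.0563 to 0.114). ADIRF was also lost without siNT MG132 library 2 or siJMJD6 library 1 (0.124 and 0.127) and with sample weights (0.0839), and ZFAND2A without siJMJD6 library 2 (−0.89, 0.0626). Without siJMJD6 library 1 HSPA8 had −1.09. Without the filter HSPA8, ADIRF and ZFAND2A were not called (0.0582 to 0.142).

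After heat shock the same knockdown was compared in 3 siJMJD6 and 3 siNT libraries. HSP90AA1 fell from 20909 ± 1138 to 3939 ± 217 normalised counts (−2.41 ± 0.069, adjusted p = 6.72e-25). BAG3 (−0.93 ± 0.094), HSPA1B (−0.68 ± 0.083), DNAJB1 (−0.48 ± 0.078), HSPH1 (−0.38 ± 0.075) and HSPB1 (−0.24 ± 0.077) fell as well (adjusted p from 4e-10 to 0.00993). HSPA1A, which is nearly identical in sequence to HSPA1B, rose by 0.21 ± 0.084 (adjusted p = 0.0419) although its groups overlapped. HSF1 rose by 0.25 ± 0.073 (adjusted p = 0.00573), and HSPA8 had 0.15 ± 0.11 (adjusted p = 0.272). In all 4557 of 9831 genes were called, 2107 higher and 2450 lower, of which 754 and 874 changed at least 2-fold. That is 46.4% of tested genes, with 24.9% lower, and list counts in this comparison are to be read against these shares.

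Folding genes of several compartments fell with siJMJD6 after heat shock. Of 37 cytosolic chaperones 20 fell, 3 rose and 14 were not called (21 fell adjusted over the list alone, camera adjusted p = 0.00192, 0.24 with an estimated correlation). Among those that fell were the HSP60 gene HSPD1, a mitochondrial member of that list (−1.24 ± 0.065), the HSP70 to HSP90 adaptor STIP1 (−0.92 ± 0.085) and the HSP90 co-chaperone PTGES3 (−0.70 ± 0.066). Of 20 ER genes 12 fell, 0 rose and 8 were not called (13 fell adjusted over the list alone, camera adjusted p = 0.000138, 0.152 with an estimated correlation). They included HSPA5 at −1.39 ± 0.066, HERPUD1 at −1.72 ± 0.097, SDF2L1 at −1.13 ± 0.085 and MANF at −1.03 ± 0.090. In the list of TRiC and prefoldin subunits 8 of 14 fell and 2 rose, with VBP1 at −2.77 ± 0.16 and CCT3 at −0.47 ± 0.084 (camera adjusted p = 0.221). Of 34 proteasome subunits 12 fell and 4 rose, with PSMD8 of the regulatory cap at −1.70 ± 0.084 (camera adjusted p = 0.067). Of 19 ubiquitin and autophagy genes 7 fell and 3 rose, with ZFAND2A at −1.18 ± 0.16 (camera adjusted p = 0.638).

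ATF4 and CHOP targets and mitotic genes were the lists that fell most firmly with siJMJD6 against siNT after heat shock. Of 23 ATF4 and CHOP targets 19 fell, 2 rose and 2 were not called (camera adjusted p = 1.15e-05, held with an estimated correlation at 0.0284). Those that fell included DDIT4 at −1.97 ± 0.11, SLC7A11 at −1.88 ± 0.11, the stress kinase-like TRIB3 at −1.85 ± 0.14 and the stress regulator NUPR1 at −1.25 ± 0.090. ATF4 itself, among the 19 that fell and again named only after the other members were seen, changed by −1.14 ± 0.092, adjusted p = 2.07e-12. Of 24 mitotic genes 17 fell, 0 rose and 7 were not called (7.78e-05, held at 0.0284). Their largest called effects included the cyclin CCNB1 at −1.54 ± 0.15, AURKA at −1.48 ± 0.12, PLK1 at −1.54 ± 0.17 and BIRC5 of the spindle at −0.93 ± 0.094. Among 21 S phase genes 10 fell and 4 rose (camera adjusted p = 0.329). Thymidylate synthase TYMS had −1.63 ± 0.11, RRM1 −1.39 ± 0.14 and RRM2, its partner subunit, 1.01 ± 0.14. All 4 tested metallothioneins fell, with MT1X at −1.48 ± 0.18 and MT2A at −0.76 ± 0.083 (camera adjusted p = 0.0213, 0.304 with an estimated correlation). Interferon-response genes rose in 7 of 11 cases and fell in 0, IFI6 by 2.09 ± 0.25 and ISG15 by 0.92 ± 0.095 (0.00486, 0.106).

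The largest rises with siJMJD6 after heat shock were in the stress-linked reductase gene DHRS2 (3.77 ± 0.25), SNAR-G1 (3.43 ± 0.23) and its near-copy SNAR-F (3.17 ± 0.24). They were followed by PCYOX1L, related to a lipid-handling oxidase (3.11 ± 0.21), the inhibitor of differentiation ID3 (3.002 ± 0.17) and the histone gene HIST1H2BD (2.97 ± 0.24). Beside JMJD6 (−4.31 ± 0.18) the largest falls were in ITPK1 (−3.62 ± 0.22), RNU5F-1 (−3.11 ± 0.18) and PRC1 of the dividing cell's midzone (−2.79 ± 0.23). ATP5G1, a subunit of the mitochondrial ATP synthase, fell from 1489 ± 128 to 164 ± 14.7 normalised counts (−3.18 ± 0.087, adjusted p = 2.56e-25). RHOA, a GTPase of the cytoskeleton, fell from 534 ± 22.4 to 66.8 ± 8.28 (−2.99 ± 0.11, adjusted p = 5.09e-22). HSPA1A was not called without siNT basal library 1 (adjusted p = 0.0538), siNT heat shock library 1 (0.12, adjusted p = 0.264), siJMJD6 library 2 (0.22) or 3 (0.172), nor without the filter on low values (0.0561). HSPB1 was not called under quantile normalisation (0.0815).

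**Figure D2:**
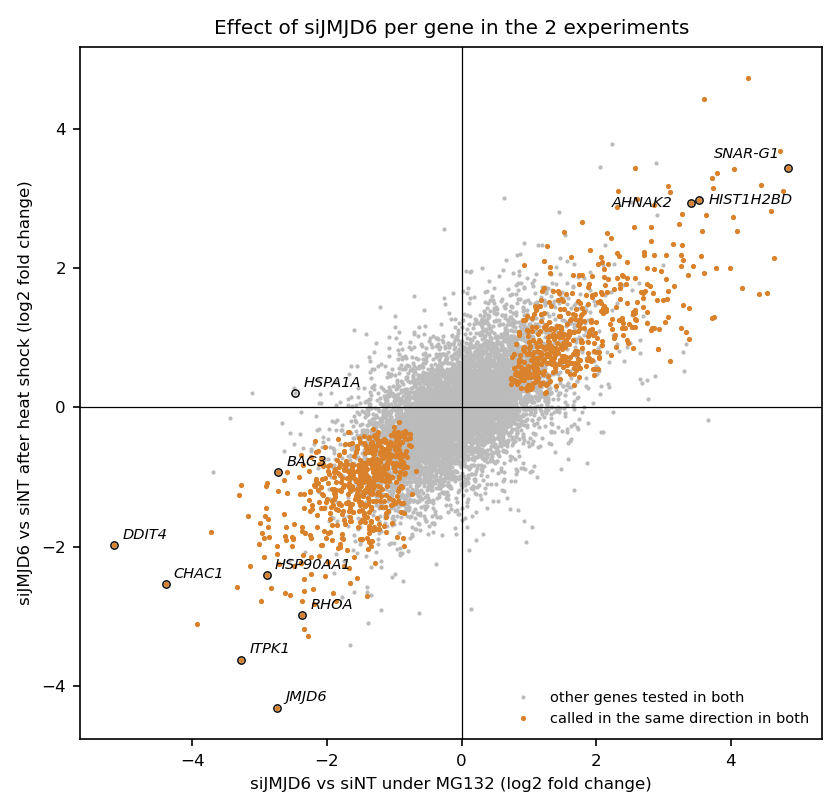
Effect of siJMJD6 on each of 9379 genes tested in both tables, under MG132 (horizontal) and after heat shock (vertical), with genes called in the same direction in both in orange. Across genes r was 0.70, and 575 genes were called lower and 488 higher in both tables.

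The effects of siJMJD6 under MG132 and after heat shock come from comparisons that share no library. Of 711 genes that fell with siJMJD6 under MG132 and were tested in both tables, 575 also fell after heat shock (181 expected, one-sided exact Fisher test p = 2.17e-231), as HSP90AA1, DDIT4, AURKA and ITPK1 did, and 6 rose. Of 580 that rose under MG132, 488 also rose after heat shock (124 expected, exact p = 2.3e-249), as SNAR-G1 and IFI6 did, and 7 fell. Seen from the heat shock table, the 575 were part of 2391 genes that fell there and the 488 part of 2001 that rose, so most genes called after heat shock were not called under MG132. Across 9379 genes the effects correlated at r = 0.70 (Spearman 0.66) and 74% had the same sign. Genes are not independent of one another, so these p-values are smaller than the evidence warrants.

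HSF1 KO cells were compared with siNT cells under MG132 (2 libraries each), to ask which of the same genes depend on HSF1. HSPA1A fell from 10263 ± 3832 to 205 ± 33.7 normalised counts (−5.60 ± 0.38, adjusted p = 4.96e-06), and HSPH1 from 1274 ± 165 to 59.4 ± 25.6 (−4.46 ± 0.33). HSPA1B (−5.12 ± 0.30), BAG3 (−3.78 ± 0.43), DNAJB1 (−2.73 ± 0.25), HSPB1 (−2.64 ± 0.25) and HSP90AA1 (−2.43 ± 0.23) fell as well, and adjusted p for these 7 genes lay between 1.84e-06 and 0.000409. HSPA8 had −0.63 ± 0.34 (adjusted p = 0.478) and JMJD6 −0.87 ± 0.32 (adjusted p = 0.267). Neither was called. In all 125 of 9778 genes were called, 27 higher and 98 lower, each by at least 2-fold. KO cells also differed from siNT cells in line and in transfection, so no difference can be assigned to HSF1 alone. Their titles lack the X1 or X2 tag of the other titles in that table, so separate handling of these libraries cannot be excluded.

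Of 34 cytosolic chaperones in HSF1 KO 17 fell, 0 rose and 17 were not called (23 fell adjusted over the list alone), and camera gave adjusted p = 1.45e-19, and adjusted p = 0.087 with an estimated correlation. The secreted stress cytokine GDF15 rose from 1124 ± 917 to 18950.5 ± 3852 normalised counts (4.35 ± 0.53, adjusted p = 0.000628), TXNIP rose by 3.45 ± 0.30, adjusted p = 4.81e-05 and BTG1, which slows cell growth, by 1.75 ± 0.24, adjusted p = 0.00152. RAB31 of vesicle traffic fell (−4.86 ± 0.40, adjusted p = 3.33e-05). Of 23 ATF4 and CHOP targets 2 rose, GDF15 and CHAC1, and 0 fell. ATF4 itself had −0.041 ± 0.27 in KO (adjusted p = 0.972, chosen after its siJMJD6 values were seen). The growth arrest list had 1 of 14 higher and 0 lower (camera adjusted p = 0.00747, 0.518 with an estimated correlation). S phase genes had 0 of 21 called by limma and 3 higher at an unadjusted p under 0.05 (0.0158, 0.899), with GINS2 of the replication fork at 1.19 ± 0.46. No proteasome subunit, ER gene or mitotic gene was called by limma (0 of 34, 0 of 20 and 0 of 24, with 3, 2 and 0 higher at an unadjusted p under 0.05).

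Further HSF1 KO calls were less firm. The cancer-testis antigen CTAG2 had 4.68 ± 0.85, adjusted p = 0.0162, resting on KO library B (1003 normalised counts, against 79.3 in library A), and without that library 2.86 (adjusted p = 0.188), or 4.06 without siNT MG132 library 1 (0.168). The matrix regulator CTGF (2.82 ± 0.63) lost its call when any 1 of the 4 libraries compared was left out (adjusted p from 0.146 to 0.436), as did UBB (−1.41 ± 0.25, 0.0745 to 0.18) and ZFAND2A (−1.54 ± 0.33, 0.136 to 0.306). ZFAND2A also lost it without DMSO library 1 (0.0553) and under TMM (0.0513). CHAC1 (1.17 ± 0.26) lost it without any 1 of the 4 libraries compared (0.148 to 0.444), without either DMSO library (0.068 and 0.0719) and under TMM (0.0589). The TGF-β feedback gene PMEPA1 (2.06 ± 0.34) lost it without siNT MG132 library 1 or either KO library (0.0877 to 0.129), and the G protein regulator RGS2 (1.89 ± 0.31) without siNT MG132 library 2 or either KO library (0.0951 to 0.132). APCDD1L, related to a Wnt inhibitor (−4.36 ± 0.87), lost it without siNT MG132 library 1 or 2 or KO library A (0.105 to 0.284), with −2.34 (0.061) at a pseudocount of 10. The actin bundler LCP1 had 0.0178 ± 0.0252 against 55.6 ± 56.7 normalised counts. It was not called without siNT MG132 library 2 (−4.02, 0.216), KO library A (0.193) or B (0.214), or at a pseudocount of 10 (−2.37, 0.21). Without the filter none of these 9 genes was called (0.107 to 0.253), and with a filter at 50 CTGF, ZFAND2A, CHAC1, APCDD1L and LCP1 were not (0.0511 to 0.0745). CTGF was also lost at a pseudocount of 0.5 (0.0528), under TMM (0.0516) and under quantile normalisation (0.0641).

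The HSF1 KO counts moved with the choice of libraries and settings. Called genes numbered 43 without siNT MG132 library 1, 53 without siNT MG132 library 2 or either KO library, 29 without the filter on low values, 70 with a filter at 50, 213 in a fit of these 4 libraries alone and 325 with a block for the replicate number. Chaperone calls were 10 and 9 without siNT MG132 libraries 1 and 2, 9 without KO library B and 9 without the filter, which also ended the calls of BAG3 (0.071) and GDF15 (0.107).

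The same KO cells were set against siJMJD6 cells under MG132 (2 libraries each), to show where loss of HSF1 and knockdown of JMJD6 differ. HSPH1 (−3.54 ± 0.33, adjusted p = 3.54e-05), HSPB1 (−2.87 ± 0.25, adjusted p = 2.38e-05), HSPA1A (−3.13 ± 0.38) and HSPA1B (−2.74 ± 0.30) were lower in KO cells. HSP90AA1 (0.47 ± 0.23), DNAJB1 (−0.55 ± 0.25) and BAG3 (−1.05 ± 0.43) were not called (adjusted p from 0.0997 to 0.169). ATF4 targets were higher in KO cells, CHAC1 by 5.57 ± 0.26, adjusted p = 8.69e-08, DDIT4 by 4.80 ± 0.29, GDF15 by 4.13 ± 0.53, TRIB3 by 3.80 ± 0.53 and ASNS by 2.81 ± 0.30. JMJD6 was higher by 1.87 ± 0.32 and HSF1 had −3.51 ± 0.27. In all 2033 of 9778 genes were called, 1086 higher and 947 lower in KO cells (934 and 834 at least 2-fold). More were lower than higher without KO library A (365 and 289) or B (410 and 337), without the filter (762 and 700) and in a fit of these 4 libraries alone (859 and 840).

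By list, 18 of 23 ATF4 and CHOP targets were higher in KO than in siJMJD6 cells and 1 was lower (camera adjusted p = 1.1e-09, 0.508 with an estimated correlation). Of mitotic genes, 18 of 24 were higher and 0 lower (1.8e-07, 0.627), with AURKA at 2.22 ± 0.26, PLK1 at 2.19 ± 0.40 and the proliferation marker MKI67 at 1.77 ± 0.34. Of S phase genes, 12 of 21 were higher and 0 lower (7.39e-06, 0.673), with MCM7 at 1.74 ± 0.27 and TYMS at 1.82 ± 0.32. Of 34 cytosolic chaperones 14 were lower and 1 higher, namely HSPA8 (1.02 ± 0.34, adjusted p = 0.0489; camera 3.72e-05, 0.508). The largest falls were in SNAR-F (−6.85 ± 0.87), LCP1 (−5.58 ± 1.06), the secreted chaperone CLU (−5.10 ± 0.43), SNAR-G1 (−4.96 ± 0.62), APCDD1L (−4.56 ± 0.87) and the matrix gene VCAN (−4.54 ± 1.01), and CTAG2 had 5.10 ± 0.85. Called genes numbered 654 and 747 without KO library A or B. HSPA8 was not called in 6 of the 8 fits that left out 1 library, with 0.46 (0.327) without siJMJD6 library 1 and 1.58 without siJMJD6 library 2. Nor was it called at a pseudocount of 0.5 (0.051), without the filter (0.134), under TMM (0.0547), under quantile normalisation (0.0506) or in a fit of the 4 libraries alone (0.0695). VCAN was not called without the filter (0.0756) and had −2.11 without KO library A and −6.97 without KO library B, and CTAG2 3.27 without KO library B. APCDD1L was not called without KO library A (−3.13, 0.053), and at a pseudocount of 10 LCP1 had −2.68 and APCDD1L −2.55.

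**Figure D3:**
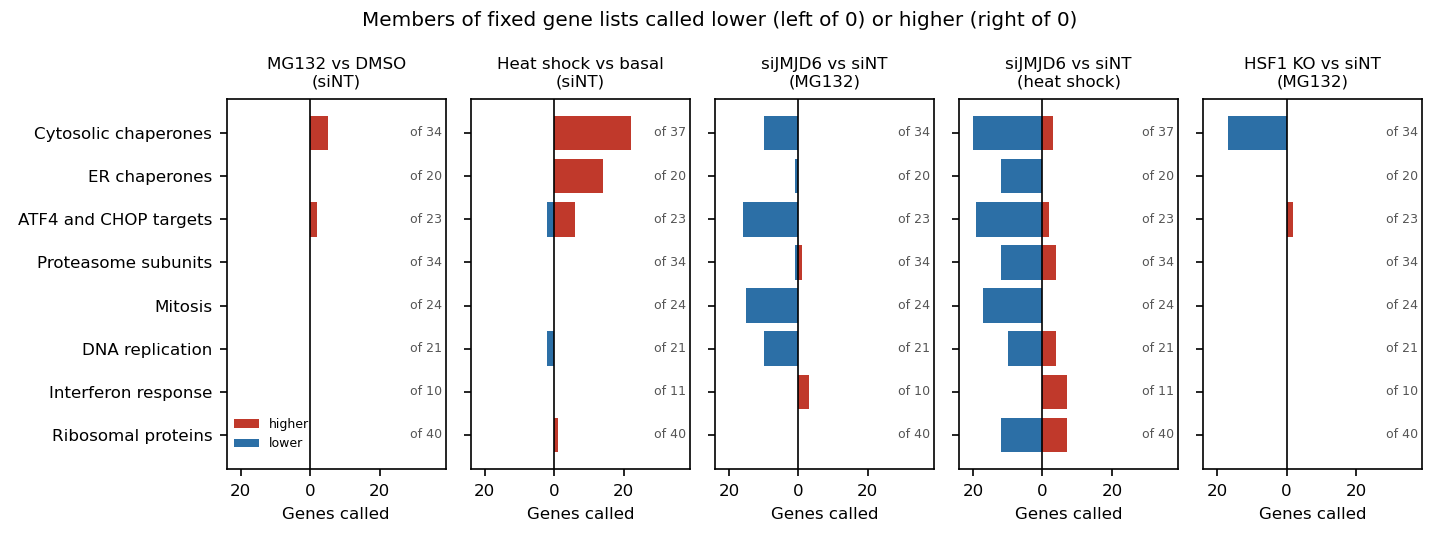
Members of 8 gene lists called higher (right) or lower (left) in 5 comparisons. Of 37 chaperones 22 rose after heat shock, and 17 of 34 fell in HSF1 KO under MG132.

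Of 20 genes raised by MG132, 16 were also raised by heat shock (0.574 expected by chance, one-sided exact Fisher test p = 5.89e-22), TBX3 and TRIM26 among them. These 16 were a small part of the 269 genes raised by heat shock and tested in both tables. Across all genes tested in both, the effects of MG132 and heat shock correlated at r = 0.20 (Spearman 0.15) and 55.3% had the same sign. Of 6 lowered by MG132, 0 were lowered by heat shock (0.0716 expected). Of the 20, 14 fell in HSF1 KO under MG132 (0.2 expected, exact p = 1.45e-24) and 13 fell with siJMJD6 under MG132 (1.47 expected, p = 7.92e-11), HSPA1A, HSPA1B, DNAJB1, BAG3 and HSP90AA1 in each case. Of 281 genes raised by heat shock 125 fell with siJMJD6 after heat shock (70 expected, exact p = 3.43e-13), among them BAG3, HSPA5 and HERPUD1, and 31 rose (60.2 expected). These 3 overlaps share their siNT stress libraries between the comparisons and part of the excess may come from that sharing. With the siNT stress libraries split, so that each served only 1 of the 2 effects, a test chosen after these overlaps were seen, the overlaps were 8 and 5 genes for KO (0.0519 and 0.0348 expected, exact p = 3.78e-17 and 9.31e-11) and 7 and 6 for siJMJD6 under MG132 (0.259 and 0.311 expected, exact p = 1.75e-09 and 1.63e-07). For siJMJD6 after heat shock they were 47 to 83 genes in 6 splits (exact p from 3.19e-10 to 4.21e-07). The covariance of the 2 effects across genes was −0.133 for siJMJD6 under MG132, −0.166 for KO and −0.0658 for siJMJD6 after heat shock, against −0.111, −0.111 and −0.0298 in groups simulated to share only their siNT libraries. With these libraries split it was −0.0533 and 0.0735 for siJMJD6 under MG132, −0.0402 and −0.00404 for KO, and −0.041 to −0.0307 for siJMJD6 after heat shock.

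Overlaps between the tables share no library. Of 269 genes raised by heat shock and tested in both tables, 38 fell in HSF1 KO under MG132 (2.67 expected, exact Fisher p = 7.7e-35) and 40 fell with siJMJD6 under MG132 (20.4 expected, p = 2.68e-05), with median effects of −0.48 and −0.33 over all 269. Of the 20 MG132-raised genes, 11 fell with siJMJD6 after heat shock (5.1 expected, exact p = 0.0046), a call that was lost without siNT MG132 library 1 (5 genes, exact p = 0.0528) and without the filter on low values (2 genes, 0.235). Unlike these, the overlap of genes lowered by siJMJD6 and in KO lies within the MG132 table, and its 2 comparisons share their siNT MG132 libraries. It held 13 genes, from 719 and 98 (7.21 expected, exact p = 0.0268), and 11 under TMM (exact p = 0.0639). The exact test takes the 2 comparisons as independent, which they are not, so its p-values for this overlap do not measure a common effect. That overlap was 36 genes with a block for the replicate number (exact p = 0.00411) and 17 with a pseudocount of 10 (3.28e-05). The covariance of the 2 effects, 0.106, was close to the 0.111 simulated for groups that only share their siNT libraries. These counts moved when 1 library was left out. The 40 became 19 without siNT MG132 library 1 and 26 without library 2, the 38 became 17 and 15 without these and 20 and 19 without KO libraries A and B, and the 11 became 5 without siNT MG132 library 1 and 6 without either DMSO library. The 13 genes lowered in both became 7 without siNT MG132 library 1 or 2 or KO library A or B, and 8 without DMSO library 1. The 13 and 14 MG132-raised genes that fell with siJMJD6 and in KO became 5 each without siNT MG132 library 1, 8 each without library 2, 6 and 7 without DMSO libraries 1 and 2, 8 and 9 without KO library A, and 8 and 10 without KO library B. Without the filter on low values the 5 overlaps with stress-raised genes that draw on the MG132 table were 24 (of 40), 12 (of 38), 2 (of 11), 3 (of 13) and 2 (of 14).

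Under MG132 limma called 0 members in each of the lists of TRiC and prefoldin (14 tested, 0 at an unadjusted p under 0.05), metallothioneins (2, 0), NF-κB cytokines (5, 0), interferon response (10, 0), S phase (21, 2), cholesterol synthesis (19, 2), hypoxia (17, 2), JmjC oxygenases (21, 3), ribosomal proteins (40, 1), epithelial identity (9, 1), mesenchymal identity (8, 0), androgen receptor-positive prostate (4, 0) and blood and immune genes (2, 0). Immediate-early genes had 1 of 18 higher and 1 lower, and growth arrest genes 1 of 14 higher and 0 lower. After heat shock 1 of 40 ribosomal protein genes rose (RPS9, 0.31 ± 0.069), 1 of 18 hypoxia genes rose, the prolyl hydroxylase gene P4HA1 (0.45 ± 0.082), and 3 of 19 ubiquitin and autophagy genes rose. Limma called 0 of 9 NF-κB, 0 of 11 interferon, 0 of 24 mitotic, 0 of 19 cholesterol and 0 of 4 prostate genes (1, 1, 0, 6 and 3 at an unadjusted p under 0.05). With siJMJD6 after heat shock 12 of 40 ribosomal protein genes fell and 7 rose, 9 of 22 splicing regulators fell and 2 rose (HNRNPA1, −1.02 ± 0.084), and 7 of 19 cholesterol genes fell and 3 rose (INSIG1, −1.14 ± 0.12). Of 16 NRF2 targets 9 fell and 5 rose (the iron store FTL, 1.28 ± 0.090, and TXNRD1 of thioredoxin, −1.14 ± 0.10). Of the others, 7 hypoxia genes fell and 5 rose, 7 JmjC genes fell and 4 rose, and 7 immediate-early genes fell and 4 rose (KLF6, −1.30 ± 0.12). In the NF-κB list 3 fell (NFKB1, −1.01 ± 0.24), while 4 growth arrest genes rose and 2 fell (CDKN1A, a brake on cyclin-dependent kinases, 0.97 ± 0.21). In the identity lists 4 of 9 epithelial genes rose and 1 fell (KRT8, 1.34 ± 0.21), 2 mesenchymal genes rose and 2 fell, and 1 prostate gene rose, HOXB13 (0.85 ± 0.11). In this siJMJD6 comparison camera called none of the lists just given (adjusted p from 0.337 to 0.999). There 46.4% of all tested genes were called and 24.9% fell. The list of genes encoded by mitochondrial DNA had 0 members in the tables.

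In some lists median, mean and camera direction differed in sign, all without a camera call. Under MG132 these were interferon genes (median 0.098, mean 0.027, camera lower), hypoxia genes (0.061, −0.13) and mesenchymal genes (0.0099, −0.082). With siJMJD6 under MG132 they were ER genes (0.027, −0.15), hypoxia genes (−0.20, 0.13), ribosomal proteins (−0.062, −0.018, camera higher) and prostate genes (−0.082, 0.16). In KO against siNT they were ubiquitin and autophagy (0.022, −0.092), NF-κB (−0.19, 0.28), hypoxia (0.064, 0.019, camera lower), epithelial (−0.084, 0.22) and prostate genes (0.33, −0.043), and against siJMJD6 TRiC and prefoldin (−0.32, 0.042), ER (−0.0028, 0.13), hypoxia (0.10, −0.12) and epithelial genes (0.12, 0.082, camera lower). After heat shock mesenchymal genes had 0.11 and 0.041 with camera lower. With siJMJD6 after heat shock they were ubiquitin and autophagy (0.032, −0.24), ribosomal proteins (0.00099, −0.015), prostate genes (−0.14, 0.077), and mesenchymal (−0.12, −0.17) and blood genes (−0.16, −0.16) with camera higher.

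The share of tested genes whose libraries did not overlap between the groups was 36.3% for MG132, 53.1% for siJMJD6 under MG132, 45.3% for KO against siNT and 61.1% for KO against siJMJD6, where 2 against 2 libraries give 33.3% by chance. It was 19.8% for heat shock and 54% for siJMJD6 after heat shock, where 3 against 3 give 10%. Genes with an unadjusted p under 0.05 numbered 553, 2769, 1253, 3421, 1482 and 5174 in the same order.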

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

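Tests of the HSPA1A to HSPA1B ratio, of scaling, of the stress overlaps between the 2 tables and of those with split siNT libraries were chosen only after the result was seen; the others were written before their result. For 5 of 129 named genes every siJMJD6 library lay on one side of siNT under MG132 and on the opposite side after heat shock, and the difference between the 2 experiments was not tested. None of the 5 was called under MG132. The effect under MG132 and after heat shock was 0.60 (adjusted p = 0.366) and −1.19 for DUSP5, −0.35 (0.489) and 0.98 for GADD45B, 0.23 (0.589) and −0.24 for HSPB1, 0.84 (0.228) and −1.48 for MT1X, and 0.52 (0.174) and −0.76 for MT2A.

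The first pattern weighed is that siJMJD6 lowered and raised many genes, and most of those called under MG132 (575 of 711 lower, 488 of 580 higher) were among the 2391 and 2001 called after heat shock. A single seed of the siRNA matched in 3' UTRs does not account for most of the 575 lower genes. The most enriched 7-base word was in 20.9% of the 3' UTRs of genes lower in both tables and 12% of uncalled ones. That is an excess of 8.95 points, against up to 7.51 points in 20 random sets. Several seeds, as in a pool of siRNAs, and changes passed on by a few off-target genes could not be seen this way. A weaker seed effect on part of the genes could remain, since an excess of 8.95 points is above the random sets. Depth after heat shock stays open, with means of 2.11 M in siNT and 1.62 M in siJMJD6 libraries. The effect correlated at r = 0.135 with the difference between the shallowest and the deepest siNT basal library, between the bounds of 0.1 and 0.3 set for deciding it. Depth estimates of those basal libraries are uncertain. Under MG132 mean depths were 1.71 M in siNT and siJMJD6 libraries alike, which argues against depth as the source of the effects there. The choice between the authors' scaling and quantile normalisation is unlikely to make the pattern, as 95.9% of the calls kept their direction under the latter. Median effects over all tested genes after heat shock were −0.034 and −0.0033 under these scalings. A shift common to all genes would therefore not show.

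The second pattern is that genes raised by stress were lower with siJMJD6 or in HSF1 KO, where a high chance value in the shared siNT libraries could make a gene look raised and then lowered. How much of the overlaps of 13 (siJMJD6 under MG132), 14 (KO) and 125 genes (siJMJD6 after heat shock) comes from that cannot be told, since groups simulated without an effect had almost no lower calls (0.25, 0.34 and 0.06 on average) and simulated sharing alone gave a covariance of −0.111, −0.111 and −0.0298, against −0.133, −0.166 and −0.0658 observed and −0.0533 and 0.0735, −0.0402 and −0.00404, and −0.041 to −0.0307 with the siNT stress libraries split. Sharing is unlikely to be the whole cause, since with the siNT stress libraries split between the 2 effects the overlaps were at least 6 (siJMJD6 under MG132), 5 (KO) and 47 genes (siJMJD6 after heat shock), with an exact p of at most 1.63e-07, 9.31e-11 and 4.21e-07 in the 2, 2 and 6 splits. Between the tables, which share no library, 40 and 38 of 269 genes raised by heat shock were lower with siJMJD6 under MG132 and in KO (20.4 and 2.67 expected), with an exact p of at most 0.000524 and 1.11e-14 in every setting, although the counts were 19 and 17 without siNT MG132 library 1, 26 and 15 without library 2 and, for KO, 20 and 19 without KO libraries A and B, while the 11 of 20 MG132-raised genes lower with siJMJD6 after heat shock (exact p = 0.0046) became 5 (0.0528) without siNT MG132 library 1, 6 (0.0217) without either DMSO library and 2 (0.235) without the filter. An effect present before stress could give the same overlaps, and no library analysed here tests that.

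The third pattern is that HSPA1B fell with siJMJD6 after heat shock and HSPA1A did not. A random split of reads between the near-identical copies could not be excluded. The log2 ratio of HSPA1A to HSPA1B moved from 0.12 ± 0.17 to 1.003 ± 0.072 (n = 3 each), by 6.73 SDs, with an exact p of 0.1, the smallest that 3 against 3 can give, but this restates the pattern in the same libraries. Under MG132 the ratio was 1.16 and 1.99 in siJMJD6 libraries and 1.62 and 1.71 in siNT libraries, without a shift to one side. Most sequence near the 3' end tells the copies apart: 22.2% of 50-base windows in the last 500 bases of HSPA1A, and 1.11% of those of HSPA1B, also occur in the other copy. These values argue against 3' ends that are alike throughout. Where the tags lay and how reads matching both copies were counted is not given. The windows therefore do not exclude a random split of some reads.

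Other splits of the heat shock libraries into 3 and 3 gave 0 calls at most. For heat shock against basal 1 of 10 splits, the real one, gave 367 calls (1441 genes at an unadjusted p under 0.05, against at most 637), and for siJMJD6 against siNT 1 of 10, the real one, gave 4610 (5248 against at most 165). With 10 splits no share under 0.05 can be reached. Every other split also mixes the 2 groups, so a real difference between them raises the spread and lowers the calls. The 0 calls therefore do not show what groups without a difference would give.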

How the results depend on the processing

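Pseudocounts of 0.5 and 10, TMM and quantile normalisation moved 0 of 18 counts by over 1.5 times. TMM gave an overlap of 11 genes lower with siJMJD6 and in KO (exact p = 0.0639, against 13 and 0.0268). These 2 comparisons share siNT libraries, so that p does not measure a common effect. TMM also changed the split of KO against siJMJD6 from 1086 higher and 947 lower to 973 and 972. Settings below were chosen before the data were examined except sample weights, which were chosen after. The planned tests on whole counts, with DESeq2 and edgeR, were not run because whole reads could not be recovered in all libraries. Where a fit leaves 1 library in a group, that library is assumed to vary like the other groups.

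Without a filter on low values called genes numbered 6 (26) for MG132, 675 (1327) for siJMJD6 under MG132 and 29 (125) for HSF1 KO, with the count of the fixed analysis in brackets. Chaperone calls were 2 (5) for MG132 and 9 (17) for KO. Overlaps were 3 (13) for MG132-raised genes lower with siJMJD6 under MG132, 2 (14) in KO and 2 (11) with siJMJD6 after heat shock, 24 (40) for heat-shock-raised genes lower with siJMJD6 under MG132 and 12 (38) in KO, and 6 (13) for genes lower with siJMJD6 and in KO. This setting tests more genes at low level, which changes both the trend and the adjustment. A filter at 50 gave 70 KO calls, a fit of only the 2 groups compared gave 687 siJMJD6 calls under MG132 and 213 KO calls, and sample weights gave 696 siJMJD6 calls under MG132. The cause was not tested in these cases.

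A block for the replicate number gave 46 calls for MG132 and 325 for KO, with overlaps of 67 (heat-shock-raised, lower with siJMJD6 under MG132), 63 (in KO), 20 (MG132-raised, lower with siJMJD6 after heat shock) and 36 (lower with both). The block also gave 1976 calls for siJMJD6 under MG132 (1327 without it) and 2756 for KO against siJMJD6 (2033 without it). Deviations from the group means of same-number libraries correlated across genes at r = 0.37, 0.32 and 0.04 in the MG132 table and −0.03 to 0.09 in the heat shock table. By these deviations a library of the heat shock table matched its own number best in 7 of 18 checks (6 by chance). That check did not cover the MG132 table, where the r of 0.37 and 0.32 leave a pairing possible. Titles of the siNT and siJMJD6 libraries of the MG132 table carry a tag, X1 or X2, that recurs across groups and was read as the replicate number. KO titles lack it. The labels do not say what the tag means, so the fixed analysis had no block, and an ignored pairing in that table cannot be excluded.

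With each library left out in turn, calls ranged from 10 to 31 for MG132, 351 to 1268 for siJMJD6 under MG132, 43 to 185 for KO against siNT, 654 to 2019 for KO against siJMJD6, 273 to 428 for heat shock and 3946 to 4705 for siJMJD6 after heat shock. Chaperone calls ranged from 3 to 5, 6 to 10 and 9 to 19 in the first 3 of these, and from 18 to 23 and 21 to 25 in the heat shock table. Overlaps ranged from 5 to 11 (MG132-raised, lower with siJMJD6 under MG132), 5 to 15 (in KO), 5 to 12 (with siJMJD6 after heat shock), 85 to 125 (heat-shock-raised, lower with siJMJD6 after heat shock), 19 to 49 (under MG132), 15 to 48 (in KO) and 7 to 18 (lower with both). Of these counts 131 stayed within 1.5 times and 45 did not. Which library was left out mattered: siJMJD6 calls under MG132 were 351 without siNT library 1 and 715 without library 2, and KO calls were 185 and 184, against 125, without siJMJD6 libraries 1 and 2. The overlap of genes lower with both, whose comparisons share siNT libraries, was 8 genes without DMSO library 1. The overlap of MG132-raised genes lower with siJMJD6 after heat shock was 5 genes without siNT MG132 library 1. It was 2 without the filter and lost its call there (exact p = 0.235). The cause was not tested.

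Of 360 results for named genes 118 lost a call in some setting and 2 changed sign, neither of them called. HSF1 after heat shock (0.0078) had −0.045 with TMM, −0.044 with quantile normalisation, −0.011 with sample weights and −0.029 to 0.040 with 1 library left out. HSPA8 after heat shock (0.0056) had −0.047, −0.0010 and −0.044 in the same settings and −0.15 to 0.12 with 1 library left out. The cause was not tested. Other settings ended 70 calls (no filter), 24 (only the 2 groups), 17 (sample weights), 9 (filter at 50), 9 (quantile), 8 (TMM), 4 and 3 (pseudocounts 0.5 and 10) and 0 (block). Estimated depth, at 0.63 M to 2.93 M reads, is likely to limit genes of low level most, which was not tested by level.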

Other observations

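All groups of genes here were chosen after their values were seen. No test of enrichment was run on them. With siJMJD6, of 9 replication-dependent histone genes tested under MG132, whose messages normally lack a poly(A) tail, 7 rose and 1 fell (median 3.30), and of 8 tested after heat shock 6 rose and 2 fell (median 1.53), while neither stress alone nor HSF1 KO called any. All 6 tested snaR genes, short non-coding RNAs, rose under MG132 (median 3.59) and all 5 after heat shock (median 3.43), although reads may be shared between their copies. Of 86 antisense genes whose symbols end in AS1, 15 rose and 3 fell under MG132 (median 0.62). Of 77 such genes after heat shock 37 rose and 8 fell (median 0.61), counted under a strand setting not given in the sources used here. Under TMM 7 histone genes, 6 snaR genes and 15 of these antisense genes were called higher with siJMJD6 under MG132.

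MG132-treated KO and siJMJD6 cells were also set against siNT cells in DMSO, a comparison with 2 changes at once. The genes were picked by their values in the same DMSO libraries, so part of what they share with siNT cells comes from that control, and no value for genes without a change was worked out. Of 20 genes raised by MG132 in siNT cells, 6 were higher than in DMSO in KO cells as well: DDIT3 (2.49 ± 0.26, adjusted p = 0.00041), PPP1R15A (2.71 ± 0.28, 0.00041), HMOX1 (2.82 ± 0.38, 0.00239), TNFSF9 (2.20 ± 0.29, 0.00193), GADD45B (2.07 ± 0.30, 0.00338) and ZFAND2A (1.55 ± 0.33, 0.0465). HSPA1A (−2.06 ± 0.38, 0.0164) and HSPA1B (−1.42 ± 0.30, 0.0434) were below their DMSO level. In siJMJD6 cells 12 of the 20 were higher than in DMSO, among them TBX3 (1.67 ± 0.37, 0.0107), TRIM26 (1.65 ± 0.32, 0.00612), IER5 (1.81 ± 0.25, 0.000624) and HSPA1B (1.31 ± 0.30, 0.0137), and HSP90AA1 was below it (−1.39 ± 0.23, 0.00256).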
